A study of Homo sapiens with 12 samples.

How the data were processed

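The deposited table gives expression in FPKM, per the file headers, for 25122 features in 12 libraries of OCI-LY1 cells, 3 per group, made with a poly(A) mRNA kit from 1 µg of RNA. Per the submitters' processing notes HISAT2 and DESeq2 were used with hg38, and their versions and roles are not given in the sources used here. The FPKM values were analysed as given, and reads were not analysed here. Sequencing depth is unknown, since the values showed no steps of whole reads. Of the features, 19974 carried Ensembl identifiers and 5148 were assembled features without one, and 4540 had 0 in every library. Positions came from GENCODE 29 on GRCh38 and symbols from a separate reference of gene names, both through the Ensembl identifier, which gave 19413 symbols. Of these, 1000 differed from the symbol in the table, where 171 were of the LOC kind. Of all features in the table, 4771 had no symbol there.

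Values were taken as log2(FPKM+1), and features with a mean of at least 0.5 FPKM over the 12 libraries were tested: 12422, of which 10578 had a symbol and 1710 were assembled features. R 4.3.3 with limma 3.58.1 fitted 4 group means to all 12 libraries with a mean-variance trend. The 5 pairwise contrasts and the non-additive contrast (combination minus bendamustine minus rituximab plus control) were each adjusted by Benjamini-Hochberg, with calls at adjusted p under 0.05. Of the calls, 268 between bendamustine and control, 282 between combination and control and 306 between combination and rituximab were assembled features. Python 3.11.15 with pandas 2.3.3 read the annotation and matplotlib 3.10.9 drew the figures. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

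Fixed lists, 32 in number, were written down before the data were examined, and 30 with at least 5 tested members were tested by limma camera with an inter-gene correlation of 0.01. They were p53 targets, pyroptosis, cGAS and STING, interferon response, cytokines and chemokines, NF-kappaB targets, MHC class I, MHC class II, immune ligands, B cell identity, germinal centre, plasma cell differentiation, G2 and mitosis, S phase, histones, crosslink repair, BCL2 family, integrated stress response, endoplasmic reticulum stress, NRF2, heat shock, immediate early, MYC and ribosome biogenesis, ribosomal proteins, mitochondrially encoded, oxidative phosphorylation, glycolysis, cholesterol synthesis, complement and myeloid. T cell and stromal genes, with 2 and 3 tested members, were counted without camera. Some calls between bendamustine and control held with an estimated correlation, at larger camera adjusted p. Among lists that rose these were p53 targets (0.0326), interferon response (0.0102), NF-kappaB targets (0.00435), immune ligands (0.0385), S phase (0.0176) and myeloid (0.0284). Among lists that fell they were B cell identity (0.0385), germinal centre (0.0324), integrated stress response (0.00435), endoplasmic reticulum stress (0.00719) and MYC and ribosome biogenesis (0.00229). Where 1 camera value is given for a list, it is that at the preset 0.01. Named genes followed a fixed rule: the 6 largest rises and falls per pairwise contrast among called genes with a symbol, a mean of at least 2 FPKM and groups that do not overlap, up to 3 called members per list, and 20 genes chosen in advance. The text gives values for part of the genes this rule gave.

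Alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, a log2 fold change of at least 1, median-of-ratios scaling, TPM scaling, quantile normalization, limma library weights, no mean-variance trend, only the compared groups, a replicate block, leaving out each library, estimated correlation and fry for the lists, and, added after the data were examined, corrections for GC content and length and leaving out the 2 libraries of highest GC deviation. In a self-test on residuals with shuffled libraries, 200 simulated changes between bendamustine and control were recovered at 19.0% for a log2 change of 0.5, 63.7% for 1 and 89.9% for 2, with 0 of the wrong sign and a mean of 2.5 false calls over 20 simulations. For rituximab against control the mean was 164.75 false calls, because a single shuffle gave 3294. Null lists of randomly drawn genes were called 0 of 20 times. Members of such lists are not chosen for shared expression, so this does not test camera on lists with a high inter-gene correlation. Ribosomal proteins, for instance, had an estimated correlation of 0.92. The GC correction took a simulated Spearman correlation with GC content from 0.68 to 0.0023.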

Results

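RNA was measured in OCI-LY1, a human cell line from diffuse large B-cell lymphoma, in 12 libraries, 3 for each of 4 culture conditions. Control cells grew for 2.5 days without drug. Rituximab, an antibody against the B cell surface protein CD20, was given for the whole 2.5 days, at 10 µM per the labels, a unit that could not be checked here. Bendamustine, an alkylating agent that crosslinks DNA, was given at 200 µM for the last 1.5 days after 1 day without drug. In the combination, rituximab was present from the start and bendamustine was added after 1 day. The series title concerns pyroptosis, a lytic death through gasdermin pores, and the STING pathway, which senses DNA in the cytosol. Of 25122 features in the table, 12422 with a mean of at least 0.5 FPKM were tested.

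Bendamustine separated the libraries most. The leading principal component held 47% of the variance and placed the 6 libraries with bendamustine between 19.3 and 23.2 and the 6 without it between -21.6 and -19.0. The next component held 23% of the variance and followed neither drug: combination 3 lay at -37.8 and control 3 at -20.9. Combination 3 differed from the other libraries of its group with a standard deviation of 0.461 in log2(FPKM+1), against 0.274 and 0.249 for combination 1 and 2. Ribosomal protein genes made up 14.2% of FPKM in combination 3 and 13.1% in control 3, within a range of 9.91% to 14.2% over the 12 libraries. Across genes, the deviation of a library from the other 2 of its group rose with transcript GC content in control 3 (Spearman 0.66) and combination 3 (0.64). It fell with GC content in combination 1 (-0.58) and combination 2 (-0.59). Each of these was measured against a mean that includes combination 3, so their negative values and standard deviations follow in part from that library.

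**Figure D1:**
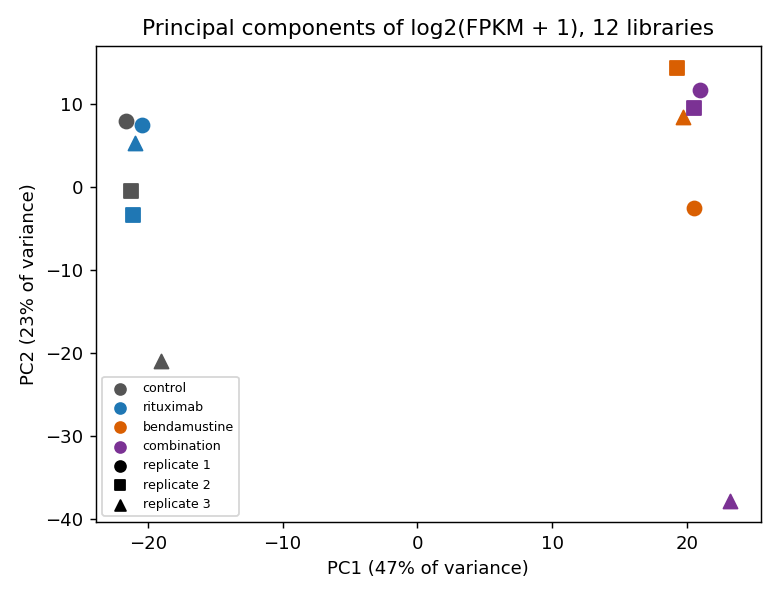
Principal components of log2(FPKM+1) over the tested genes, 12 libraries, with colour for the group and shape for the replicate number. The horizontal axis separates libraries with and without bendamustine, and combination 3 and control 3 lie low on the vertical axis.

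**Figure D2:**
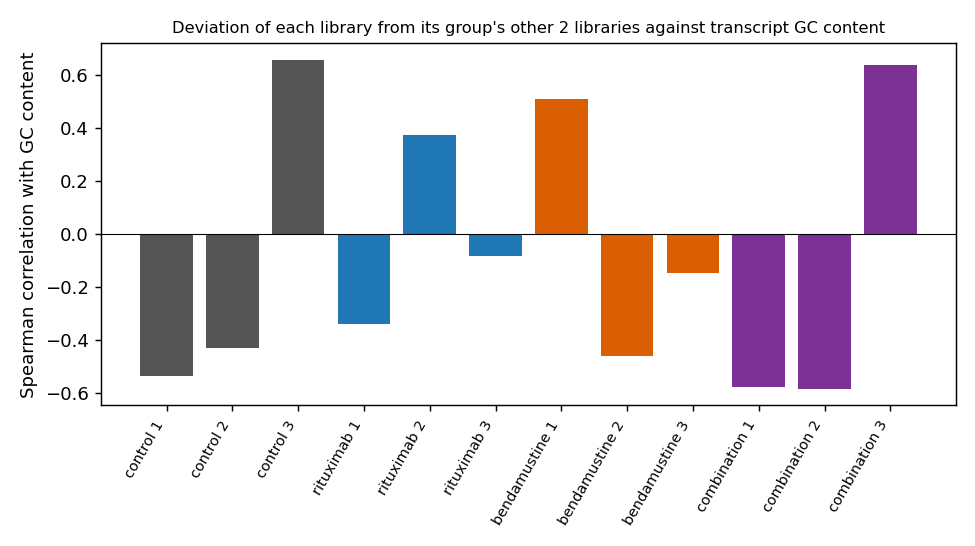
Spearman correlation, across genes, between each library's deviation from the other 2 libraries of its group and transcript GC content, 1 bar per library. Control 3 and combination 3 have the highest positive values. The references of control 1 and 2 and of combination 1 and 2 include these libraries, which contributes to their negative values.

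With bendamustine alone CHAC1, an enzyme that degrades glutathione and a target of the transcription factor ATF4, fell by 2.83 ± 0.21 SE in log2, from 29.5 ± 2.2 to 3.36 ± 1 FPKM (mean ± SD, n = 3 per group, limma adjusted p = 3.01e-06). Asparagine synthetase, ASNS, fell from 117 ± 6.7 to 30.3 ± 0.47 FPKM (log2 -1.92 ± 0.08 SE), and the serine synthesis enzyme PSAT1 from 133 ± 15 to 37.2 ± 2.3. The lymph node homing receptor CCR7 rose from 2.24 ± 0.38 to 22.6 ± 1.2 FPKM (log2 2.87 ± 0.17 SE, limma adjusted p = 7.11e-07). Other large rises were the steroid-conjugating enzyme UGT2B17 (2.36 ± 0.12), the zinc finger gene ZNF385A (2.29 ± 0.19), the retinol-oxidizing enzyme DHRS9 (2.21 ± 0.27), the trypanolytic apolipoprotein APOL1 (2.17 ± 0.12) and the chemokine CCL3L3 (2.02 ± 0.14), a multicopy gene. Falls included the inhibitory lymphocyte receptor PVRIG (-2.04 ± 0.35) and the transcription factor CEBPB (-1.84 ± 0.18). The readthrough locus NME1-NME2 had the most negative value, -4.04 ± 1.05, with 56.8 FPKM in control and 14.1 ± 24 with bendamustine. Its limma adjusted p of 0.0164 became 0.073 without bendamustine 2, 0.0741 without bendamustine 3 and 0.051 without the expression filter.

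With limma and Benjamini-Hochberg adjustment at 0.05, 2813 genes changed between bendamustine and control, 1757 higher and 1056 lower, and 254 of the 2813 changed by at least 1 in log2. Scaling moved this split: median-of-ratios scaling gave 1343 higher and 1372 lower, quantile normalization 1489 and 1445, and TPM scaling, in the other direction, 1942 and 838. On the 10712 tested genes with a GC value, GC correction gave 1738 higher and 1668 lower, against 1655 and 969 uncorrected. The count was 4256 without combination 3 and 6166 with limma library weights. Of all tested genes, 97.8% lay within 1 log2 unit of control, with a median standard error of 0.14.

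Among genes induced by p53, the transcription factor activated by DNA damage, 12 of 27 rose with bendamustine, while 21 of 25 genes of the integrated stress response fell. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose from 16.3 ± 1.4 to 63.8 ± 2.5 FPKM (log2 1.90 ± 0.11 SE, limma adjusted p = 7.11e-07), and the p53 target ZMAT3 (1.34 ± 0.18) rose with it. MDM2, which degrades p53, rose by 0.61 ± 0.15 (limma adjusted p = 0.0148), a call absent without bendamustine 2 (adjusted p = 0.0536) or bendamustine 3 (0.0526). Of 27 p53 targets tested, 12 rose and 1 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00181). Of 25 genes of the integrated stress response, the ATF4 program for amino acid shortage, 1 rose and 21 fell, the same counts adjusted over the list alone (median log2 -0.94, camera adjusted p = 6.61e-22, or 0.00435 with an estimated correlation). They included the cystine transporter SLC7A11 (-1.71 ± 0.20, 7.39 to 1.5 FPKM). Among 20 genes of endoplasmic reticulum stress, 0 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 1.57e-06), with HERPUD1 at -0.72 ± 0.09 and EDEM1 at -0.73.

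MYC, the growth-promoting transcription factor, fell from 354 ± 7.9 to 224 ± 4.5 FPKM (-0.66 ± 0.07 SE, limma adjusted p = 3.29e-05). The ribosome assembly factor RRS1 fell by 0.84 ± 0.09 SE and PPAN, another, by 0.76. Of 30 genes of MYC and ribosome biogenesis, 0 rose and 17 fell, or 0 and 20 adjusted over the list alone (camera adjusted p = 4.01e-12, or 0.00229 with an estimated correlation). Of 50 ribosomal protein genes, 0 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 3.97e-07; adjusted p = 0.467 with an estimated correlation). That list was also not called after quantile normalization (camera adjusted p = 0.349). Of 13 mitochondrially encoded genes 0 changed, and of 31 nuclear genes of oxidative phosphorylation 1 rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.639 and 0.101). Among 23 cholesterol synthesis genes the sterol carrier STARD4 rose (0.73 ± 0.18) and the sterol-sensing transcription factor SREBF2 fell (-0.49 ± 0.06), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.491).

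Of 38 interferon response genes 28 rose with bendamustine. IFIT3, which binds foreign RNA complexes, rose from 50.2 ± 1.5 to 170 ± 2.9 FPKM (1.74 ± 0.08 SE, limma adjusted p = 2.68e-07), and IFIT2 (1.65 ± 0.16) and the antiviral gene SAMD9L (1.67 ± 0.25) rose similarly. Of the 38, 28 rose and 0 fell, or 33 and 0 adjusted over the list alone (median log2 0.90, camera adjusted p = 4.5e-19, or 0.0102 with an estimated correlation). IFNB1, the type I interferon gene itself, rose from 2.19 ± 0.13 to 4.63 ± 0.82 FPKM (0.81 ± 0.15, limma adjusted p = 0.00282), and the T cell attractant CXCL10 from 3.49 ± 0.43 to 9.73 ± 1.2 (1.26 ± 0.14). STING1, the adaptor of cytosolic DNA sensing, rose from 0.0924 ± 0.032 to 1.09 ± 0.44 FPKM (0.92 ± 0.14, limma adjusted p = 0.000795), 11.8 times the control mean at low expression. STING1 passed the expression filter only through the groups with bendamustine. The DNA sensor CGAS (2.82 to 3.56 FPKM, 0.26 ± 0.12, limma adjusted p = 0.143), the kinase TBK1 (0.10, adjusted p = 0.607) and the transcription factor IRF3 (0.13, adjusted p = 0.518) did not pass. Of 19 genes of the cGAS and STING pathway, 4 rose and 0 fell, also adjusted over the list alone, with SAMHD1, a nucleotide hydrolase (0.67 ± 0.16), and the ubiquitin ligase TRIM32 (0.56 ± 0.13) among them. The list as a whole did not pass with camera, which compares it with the other tested genes (camera adjusted p = 0.118). It passed with fry, which makes no such comparison (fry adjusted p = 8.35e-06).

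Pyroptosis genes moved in both directions. CASP1, the caspase of inflammasomes, rose from 0.711 ± 0.047 to 1.79 ± 0.64 FPKM (0.68 ± 0.16 SE, limma adjusted p = 0.0112) and CASP8, the caspase of death receptors, from 10 to 18.3 (0.81 ± 0.12). GSDMD, the pore former cleaved by inflammatory caspases, rose from 21.2 ± 3.9 to 30.7 ± 0.17 FPKM (0.53 ± 0.15, limma adjusted p = 0.0256). GSDME, another pore former, had 1.18 ± 0.36 and 0.529 ± 0.37 FPKM (-0.53 ± 0.18, limma adjusted p = 0.0532), and CASP4 did not pass (-0.05, adjusted p = 0.849). Of 15 pyroptosis genes tested, 9 rose and 2 fell, or 9 and 3 adjusted over the list alone. The list did not pass relative to the other tested genes (camera adjusted p = 0.126) but passed with fry (fry adjusted p = 0.000287). NLRP3 (0 and 0.0153 FPKM), IL1B (0.027 and 0.0692) and IL18 (0.031 and 0.134) were below the expression filter. The GSDMD call ended in 7 settings: no filter (limma adjusted p = 0.0567), median-of-ratios scaling (0.0755), and without control 1 (0.0743), control 2 (0.106), bendamustine 1 (0.066), bendamustine 2 (0.0678) or bendamustine 3 (0.0724).

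With bendamustine EBI3, a cytokine subunit induced through NF-kappaB, rose from 2.35 to 11.3 FPKM (1.88 ± 0.12 SE, limma adjusted p = 9.73e-07), the signalling adaptor TRAF1 by 1.47 ± 0.09 and the transcription factor NFKB2 by 1.25 ± 0.14. Of 22 NF-kappaB targets, 15 rose and 0 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 9.26e-07). The chemokine CCL3 rose (1.54 ± 0.23) and lymphotoxin beta, LTB, fell from 114 to 47 FPKM (-1.24 ± 0.18), while the T cell attractant CCL5 did not pass (0.651 to 1.48 FPKM, limma adjusted p = 0.14). Of 13 cytokine and chemokine genes, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0387; adjusted p = 0.244 with an estimated correlation). This list call also ended without control 1 (camera adjusted p = 0.0808), control 2 (0.063), bendamustine 1 (0.0608) or combination 3 (0.0794), with a filter at 5 FPKM (0.804), a pseudocount of 0.1 (0.0502), a replicate block (0.0545) and GC correction (0.0689). Among 16 immediate early genes, 8 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.216 with an estimated correlation). The AP-1 subunits FOS (1.47 ± 0.15) and FOSB (1.12) and the phosphatase DUSP5 (1.09 ± 0.10) rose. That list was not called without bendamustine 1 (camera adjusted p = 0.0548), with a filter at 5 FPKM (0.101) or with GC correction within groups (0.0764).

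**Figure D3:**
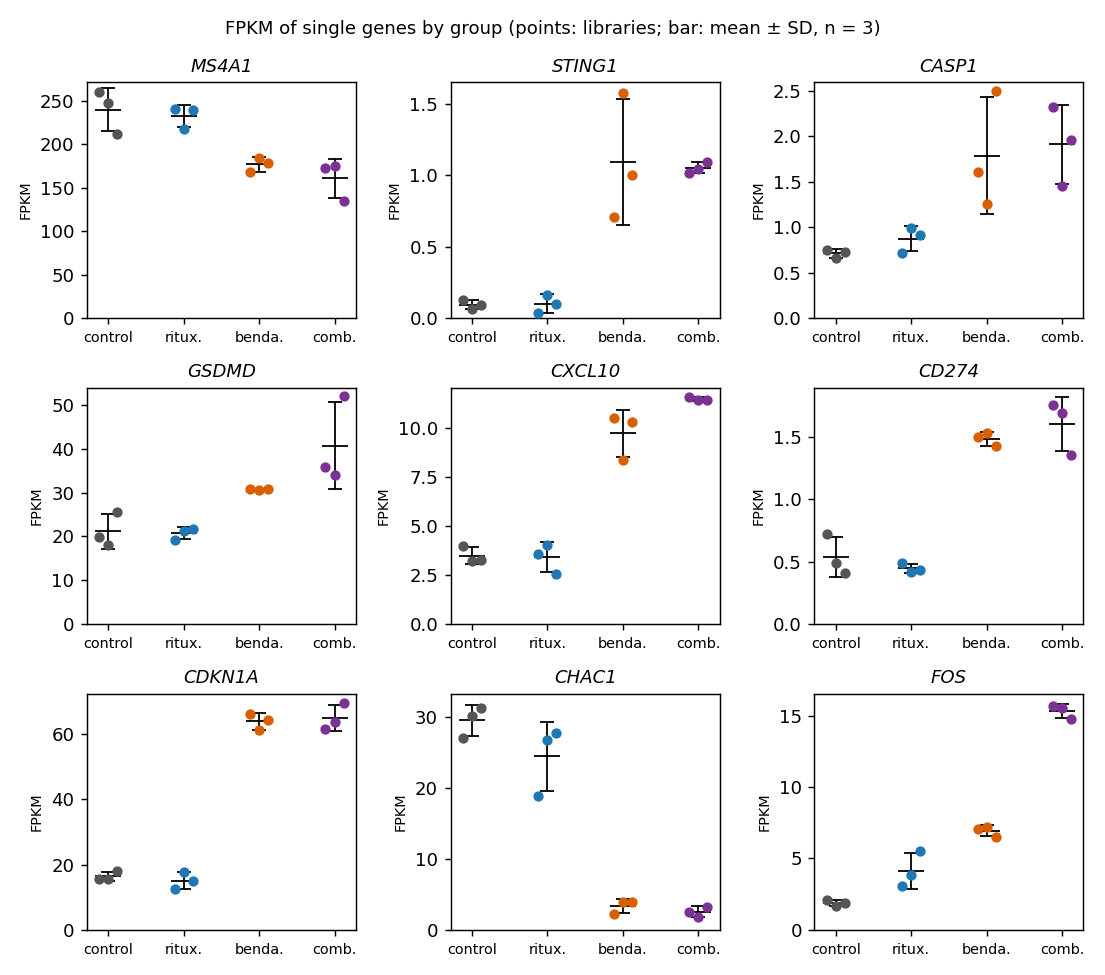
FPKM of MS4A1, STING1, CASP1, GSDMD, CXCL10, CD274, CDKN1A, CHAC1 and FOS in every library by group, with mean and standard deviation, n = 3. Libraries with bendamustine differ from those without it in STING1, CDKN1A and CHAC1, and FOS is highest in the combination.

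Of 17 ligands for other immune cells 10 rose with bendamustine, and of 25 B cell identity genes 11 fell. LGALS9, which encodes galectin-9, rose from 14 to 55.8 ± 10 FPKM (1.90 ± 0.14 SE, limma adjusted p = 3.37e-06), and the costimulatory ligands TNFSF9 (1.09 ± 0.12) and CD86 (1.04 ± 0.08) rose. CD274, which encodes PD-L1, rose from 0.538 ± 0.16 to 1.48 ± 0.055 FPKM (0.70 ± 0.12, limma adjusted p = 0.00128). Of the 17 ligands and stress signals, 10 rose and 2 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00237). The peptide transporter genes TAP1 (0.77 ± 0.07) and TAP2 (0.51 ± 0.08) rose. Of 17 genes of MHC class I presentation, 5 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0252; adjusted p = 0.378 with an estimated correlation). This call was absent with median-of-ratios scaling (camera adjusted p = 0.0565) and without control 1 (0.0544) or bendamustine 1 (0.0578). Of 13 MHC class II genes, 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0655), with the peptide-trimming protease CTSS at 0.50 ± 0.10.

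MS4A1, which encodes CD20, had 240 ± 25 FPKM in control and fell to 177 ± 8.1 with bendamustine (-0.43 ± 0.11 SE, limma adjusted p = 0.0136). It was not called with TPM scaling (limma adjusted p = 0.0817), quantile normalization (0.136), or without control 1 (0.0552), control 2 (0.0521) or bendamustine 1 (0.0535). The B cell receptor modulator CD22 fell (447 to 221 FPKM, -1.01 ± 0.09). Of 25 B cell identity genes, 5 rose and 11 fell, or 6 and 12 adjusted over the list alone (camera adjusted p = 0.00958). Of 18 germinal centre genes, 3 rose and 7 fell, or 3 and 8 adjusted over the list alone (camera adjusted p = 0.00259), with the elongation factor ELL3 (-0.92 ± 0.09) and the chromatin remodelling subunit BCL7A (-0.78 ± 0.08) among them. Some markers of myeloid cells rose in the same libraries: the lysozyme gene LYZ from 0.264 to 4.03 FPKM (1.99 ± 0.13), the integrin ITGAM (1.79 ± 0.15) and the endosomal protein CD68 (1.31 ± 0.14). Of 18 myeloid genes 5 were tested, and 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 4.17e-05). LYZ, ITGAM and AIF1 passed the expression filter only through the groups with bendamustine, so this list test was not independent of the change it tests. Among untested members S100A8, S100A9, S100A12 and MARCO had 0 FPKM in every group. In control and bendamustine CD14 had 0.097 and 0.121 FPKM, CSF1R 0.253 and 0.255, FCN1 0.137 and 0.017, and TYROBP 0.0267 and 0.584. Of 2 T cell genes tested, 0 rose and 1 fell, or 1 and 1 adjusted over the list alone. Of 3 stromal genes, 1 rose and 0 fell, the same adjusted over the list alone, the smooth muscle actin ACTA2 (5.27 to 15.1 FPKM, 1.38 ± 0.13).

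Genes of DNA replication rose and some mitotic genes fell with bendamustine. The cyclin CCNE2 rose from 7.35 to 16.1 FPKM (1.02 ± 0.20 SE, limma adjusted p = 0.00363), with thymidine kinase TK1 (0.91 ± 0.15) and the replication initiator MCM10 (0.90 ± 0.12). Of 31 S phase genes, 25 rose and 0 fell, or 29 and 0 adjusted over the list alone (camera adjusted p = 2.12e-11, or 0.0176 with an estimated correlation). The mitotic kinesin KIF20A fell from 11.6 to 5.38 FPKM (-0.98 ± 0.11) and the mitotic kinase PLK1 from 65.8 to 43.1 (-0.61). Of 36 genes of G2 and mitosis, 3 rose and 9 fell, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.00313; adjusted p = 0.207 with an estimated correlation). Of 35 crosslink repair genes, 15 rose and 2 fell, or 18 and 2 adjusted over the list alone (camera adjusted p = 0.00535; adjusted p = 0.298 with an estimated correlation). In the BCL2 family the death-promoting BMF (1.27 ± 0.09) and the protective BCL2A1 (1.14 ± 0.16) rose. Of its 24 genes, 7 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.0535 with an estimated correlation).

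Rituximab alone changed 2 features, which overlap on chromosome 17. SENP3-EIF4A1, a readthrough transcript annotated from 7563287 to 7578715 on the plus strand, rose from 4.6 ± 2.2 to 59.6 ± 24 FPKM (log2 3.45 ± 0.36 SE, n = 3 per group, limma adjusted p = 0.00594). SENP3, a SUMO protease at 7561875 to 7571969, fell from 42 ± 3 to 23.4 ± 0.51 FPKM (-0.81 ± 0.09, limma adjusted p = 0.00798). The neighbouring translation factor EIF4A1, at 7572706 to 7579005, had 804 and 667 FPKM. MS4A1, the gene of the antibody's target, had 240 ± 25 and 233 ± 13 FPKM (-0.04 ± 0.11), and STING1 (0.01) and CDKN1A (-0.12) did not pass either. With limma and Benjamini-Hochberg adjustment these 2 were the only calls, 1 higher and 1 lower. At unadjusted p under 0.05 there were 330 genes, 2.66% of those tested, below the share of 0.05 that would pass on average without any effect. A low share does not show that rituximab had no effect, since genes are not independent and the spread is shared over all groups. SENP3 was not called, which left a count of 1, without control 2 (limma adjusted p = 0.0652), control 3 (0.0654), rituximab 2 (0.0596) or rituximab 3 (0.0723). The count was 5 with no filter, 4 with only the compared groups, 4 with GC correction and a replicate block, and 27 with limma library weights.

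Cholesterol synthesis was the list that moved with rituximab alone. Of its 23 genes 20 had positive values with a median log2 of 0.12, 0 were called over all genes or adjusted over the list alone, and the list passed (camera adjusted p = 0.000737; adjusted p = 0.0487 with an estimated correlation). HMGCS1, an early enzyme of the pathway, had 51 FPKM in control and 62 with rituximab. Camera also placed 4 lists lower, none of them called with an estimated correlation: S phase (camera adjusted p = 0.0471; adjusted p = 0.607 with an estimated correlation), MYC and ribosome biogenesis (0.0437; 0.343), ribosomal proteins (0.0301; 0.889) and oxidative phosphorylation (0.0389; 0.761). Adjusted over the list alone, 1 immediate early gene rose.

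The 4 lower lists depended on single libraries. The S phase list was not called without control 1 (camera adjusted p = 0.089), control 2 (0.288), rituximab 1 (0.663), rituximab 3 (0.136) or any bendamustine library (0.0576, 0.056 and 0.0603), and the MYC list not without control 2 (0.142), control 3 (0.171), rituximab 1 (0.0788), rituximab 3 (0.166) or bendamustine 2 (0.0519). Oxidative phosphorylation was not called without control 2 (camera adjusted p = 0.0524), control 3 (0.759), rituximab 1 (0.169), rituximab 3 (0.136) or bendamustine 2 (0.0519). Ribosomal proteins were not called without rituximab 1 (camera adjusted p = 0.156) or rituximab 3 (0.136) and turned positive relative to all genes without control 3 (median 0.03).

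In the combination against control CHAC1 fell by 3.13 ± 0.21 SE (29.5 to 2.54 FPKM, limma adjusted p = 1.14e-06), SLC7A11 by 1.85 ± 0.20 and PSAT1 by 1.95. CCR7 rose by 2.95 ± 0.17 (to 24 ± 2.3 FPKM), APOL1 by 2.30 ± 0.12 and FOS from 1.87 ± 0.22 to 15.3 ± 0.49 FPKM (2.51 ± 0.15, limma adjusted p = 4.96e-07). MS4A1 fell to 161 ± 22 FPKM (-0.58 ± 0.11, limma adjusted p = 0.00272), and CDKN1A rose to 64.8 ± 4 (1.93 ± 0.11). MDM2 did not pass (34.1 and 45.5 FPKM, 0.41 ± 0.15, limma adjusted p = 0.0753). With limma and Benjamini-Hochberg adjustment, 2859 genes changed, 1725 higher and 1134 lower, 266 of them by at least 1 in log2. Median-of-ratios scaling gave 1397 higher and 1428 lower and quantile normalization 1483 and 1536. On the 10712 genes with a GC value, GC correction gave 1685 and 1712, against 1618 and 1020 uncorrected. The count of 2859 became 1290 with only the compared groups fitted and 6909 with limma library weights.

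In the combination STING1 rose to 1.05 ± 0.04 FPKM (0.91 ± 0.14 SE, limma adjusted p = 0.000814), IFNB1 to 4.82 (0.86 ± 0.15) and CXCL10 to 11.5 ± 0.085 (1.48 ± 0.14). GSDMD rose to 40.7 ± 9.9 FPKM (0.90 ± 0.15, limma adjusted p = 0.00139), CASP1 by 0.76 ± 0.16, and the membrane rupture gene NINJ1 from 0.315 to 1.64 FPKM (1.00 ± 0.18). CGAS (0.19), TBK1 (0.08), IRF3 (0.22) and CASP4 (0.22) did not pass, with limma adjusted p of 0.288, 0.683, 0.267 and 0.357. Of 15 pyroptosis genes, 9 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0456; adjusted p = 0.0929 with an estimated correlation). This list was not called without control 1 (camera adjusted p = 0.0581), control 2 (0.0517), combination 1 (0.0501) or combination 2 (0.0529). Of 19 cGAS and STING genes, 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0689, fry adjusted p = 6.4e-06). Of 38 interferon genes 32 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.92e-21, or 0.00849 with an estimated correlation), with IFI6 at 1.87 ± 0.16 and IFIT1 at 1.69 ± 0.08.

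Borderline calls in the combination were GSDME and CCL5. GSDME fell from 1.18 ± 0.36 to 0.486 ± 0.15 FPKM (-0.55 ± 0.18 SE, limma adjusted p = 0.0451). It was not called without control 1 (limma adjusted p = 0.152), control 2 (0.132), any of the rituximab libraries (0.0603, 0.0561 and 0.0605), bendamustine 3 (0.0528), combination 1 (0.0827) or combination 2 (0.134). A pseudocount of 0.1 (limma adjusted p = 0.0597), no filter (0.0747), TPM scaling (0.0566), only the compared groups (0.0832) and the replicate block (0.0527) ended it too. CCL5 rose from 0.651 to 2.07 FPKM (0.85 ± 0.26 SE, limma adjusted p = 0.0362). It was not called without control 1 (limma adjusted p = 0.0586), control 2 (0.0924), control 3 (0.0955) or combination 2 (0.131), without a filter (0.0816) or with only the compared groups (0.0582).

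Signalling and surface genes rose in the combination along with some myeloid markers. EBI3 rose by 2.11 and NFKB2 by 1.47 against control. Of 22 NF-kappaB targets 16 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 1.47e-08, or 0.00264 with an estimated correlation). LGALS9 rose by 1.98, TNFSF9 by 1.34 and CD274 by 0.76 ± 0.12 SE (limma adjusted p = 0.000692), and of 17 immune ligands 10 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.000219). FOSB rose by 1.92 ± 0.15 and the transcription factor EGR1 from 0.988 to 3.89 FPKM (1.30 ± 0.14). Of 16 immediate early genes, 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000194; adjusted p = 0.0527 with an estimated correlation). LYZ (2.20 ± 0.13) and ITGAM (1.98) rose, and of 18 myeloid genes 5 were tested and 5 rose, also adjusted over the list alone (camera adjusted p = 1.42e-05). LYZ, ITGAM and AIF1 passed the expression filter only through the groups with bendamustine, so this list test was not independent of the change it tests. TAP1 rose by 0.87 and HLA-F by 0.80, and of 17 MHC class I genes 10 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.000205; adjusted p = 0.134 with an estimated correlation).

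In the combination PAX5, the B lineage transcription factor, fell from 60.1 to 34.3 FPKM (-0.82 ± 0.16 SE, limma adjusted p = 0.0034) and CD22 fell by 1.01. Of 25 B cell genes, 3 rose and 9 fell, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.00678), and of 18 germinal centre genes 2 rose and 8 fell, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.0006). Of 25 genes of the integrated stress response, 2 rose and 21 fell, also adjusted over the list alone (camera adjusted p = 7.17e-20, or 0.00519 with an estimated correlation). Of 30 genes of MYC and ribosome biogenesis 0 rose and 16 fell, or 0 and 20 adjusted over the list alone (camera adjusted p = 1.07e-11, or 0.00261 with an estimated correlation). Of 31 S phase genes, 22 rose and 0 fell, or 24 and 0 adjusted over the list alone (camera adjusted p = 7.31e-09, or 0.0243 with an estimated correlation). Of 27 p53 targets, 10 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00287), with the ferredoxin reductase FDXR at 1.19 ± 0.17.

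Adding rituximab to bendamustine changed 0 genes with limma and Benjamini-Hochberg adjustment. At unadjusted p under 0.05 there were 442, 3.56% of those tested, below the share of 0.05 that would pass on average without any effect, which does not show that there was none. FOS (6.94 to 15.3 FPKM, log2 1.04) and EGR1 (1.41 to 3.89, log2 1.03) shared the smallest limma adjusted p, 0.0799. GSDMD had 30.7 ± 0.17 and 40.7 ± 9.9 FPKM (0.37 ± 0.15 SE, n = 3 per group, limma adjusted p = 0.903), and MS4A1 177 ± 8.1 and 161 ± 22 (-0.14 ± 0.11, adjusted p = 0.903). For STING1 the 95% confidence interval was -0.32 to 0.30 in log2, for CASP1 -0.28 to 0.43 and for CXCL10 -0.08 to 0.52. The count was 1 without rituximab 1 or rituximab 3 and 2 without bendamustine 1. It was 1 with no filter, with quantile normalization and with no mean-variance trend, and 11 with limma library weights.

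Camera called 12 lists between combination and bendamustine, and 0 of them were called with an estimated correlation. Of these lists, fry called only the immediate early genes (fry adjusted p = 0.0103). Of 16 immediate early genes 13 had positive values (median 0.24, camera adjusted p = 2.41e-09; adjusted p = 0.0623 with an estimated correlation), and 5 rose and 0 fell adjusted over the list alone against 0 over all genes. NF-kappaB targets (camera adjusted p = 0.00435; adjusted p = 0.0883 with an estimated correlation) and MHC class I (1.07e-05; 0.255) were higher. Ribosomal protein genes had 49 of 50 positive values (camera adjusted p = 3.88e-15; adjusted p = 0.394 with an estimated correlation), and without combination 3 this became 0.636. Oxidative phosphorylation (camera adjusted p = 1.76e-05; adjusted p = 0.42 with an estimated correlation) turned negative relative to all genes without combination 3 (median -0.02). Pyroptosis (camera adjusted p = 0.175) and the cGAS and STING list (0.536) did not pass, nor did they with fry (fry adjusted p = 0.465 and 0.584).

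The other 7 lists called by camera were interferon response (camera adjusted p = 0.0138; adjusted p = 0.394 with an estimated correlation), MHC class II (0.0158; 0.394), immune ligands (0.0256; 0.255), endoplasmic reticulum stress (0.0114; 0.16) and mitochondrially encoded genes (0.0334; 0.42), all higher, and S phase (0.0133; 0.394) and G2 and mitosis (0.0211; 0.394), both lower. Leaving out combination 1 ended the interferon (camera adjusted p = 0.263), ligand (0.0506) and S phase (0.164) calls. Leaving out combination 2 ended the interferon (camera adjusted p = 0.128), ligand (0.0615), endoplasmic reticulum (0.0615), mitochondrial (0.539), S phase (0.0663) and G2 (0.0865) calls. Without combination 3 the MHC class II (camera adjusted p = 0.954), ligand (0.269), endoplasmic reticulum (0.0717) and G2 (0.151) calls were absent. Without bendamustine 2 the ligand (camera adjusted p = 0.108) and mitochondrial (0.082) calls were absent, and without bendamustine 3 the MHC class II (0.0515), mitochondrial (0.0947), S phase (0.0515) and G2 (0.062) calls.

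With bendamustine on top of rituximab, 1950 genes changed in the same direction as with bendamustine without it, of 3009 and 2813 called. ASNS fell by 1.93 ± 0.08 SE (limma adjusted p = 7.82e-08, n = 3 per group), CHAC1 by 2.85 and CEBPB by 1.82. CCR7 rose by 2.85, the antimicrobial peptide CAMP from 1.96 to 17.4 ± 5.7 FPKM (2.62 ± 0.24) and the apolipoprotein APOL3 from 3.58 to 19.8 (2.19 ± 0.10). SENP3-EIF4A1 fell from 59.6 ± 24 to 2.89 ± 1.7 FPKM (-3.99 ± 0.36, limma adjusted p = 1.3e-05). MS4A1 fell by 0.54 ± 0.11, while STING1 (0.90), CXCL10 (1.52), IFNB1 (0.97), CD274 (0.84), GSDMD (0.92 ± 0.15) and the AP-1 subunit JUNB (1.25 ± 0.14) rose. CASP1 rose by 0.63 (limma adjusted p = 0.016), except without rituximab 1 (adjusted p = 0.0642) or combination 1 (0.0567). SREBF2 fell by 0.63 ± 0.06 and HMGCS1 from 62 to 41 FPKM (-0.60 ± 0.13). With limma and Benjamini-Hochberg adjustment 3009 genes changed, 1767 higher and 1242 lower, 273 by at least 1 in log2. Median-of-ratios scaling gave 1541 higher and 1444 lower and quantile normalization 1622 and 1605. On the 10712 genes with a GC value, GC and length correction gave 1850 and 1952, against 1642 and 1119 uncorrected. The count was 1998 without rituximab 1, 1976 without rituximab 3, 1653 with only the compared groups fitted and 5724 with limma library weights.

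Against rituximab alone, of 38 interferon genes 31 rose and 0 fell, or 34 and 0 adjusted over the list alone (camera adjusted p = 2.85e-21, or 0.0087 with an estimated correlation), with IFI35 at 1.67 ± 0.15 SE. Of 25 genes of the integrated stress response 1 rose and 20 fell, or 2 and 21 adjusted over the list alone (camera adjusted p = 3.18e-18, or 0.00692 with an estimated correlation). Of 15 pyroptosis genes 8 rose and 2 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0351; adjusted p = 0.0785 with an estimated correlation), and without rituximab 3 the list was not called (camera adjusted p = 0.0546). The gasdermin GSDMB rose from 4.42 to 8.14 FPKM (0.74 ± 0.15, limma adjusted p = 0.00442). Of 19 cGAS and STING genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0177; adjusted p = 0.0573 with an estimated correlation), and the list was not called with a filter at 5 FPKM (camera adjusted p = 0.0656). Its member STING1 passed the expression filter only through the groups with bendamustine. Of 23 cholesterol genes 0 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0857). Of 18 myeloid genes 5 were tested, and 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 2.9e-05). Here too LYZ, ITGAM and AIF1 passed the expression filter only through the groups with bendamustine.

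The non-additive part of the combination, its departure from the sum of the separate log2 effects, gave 0 genes with limma and Benjamini-Hochberg adjustment. At unadjusted p under 0.05 there were 429, 3.45% of those tested, below the share of 0.05 that would pass on average without any effect, which does not show that there was none. STING1 had -0.02 ± 0.20 SE with a 95% confidence interval of -0.45 to 0.42, GSDMD 0.38 ± 0.22 (-0.09 to 0.86, limma adjusted p = 0.86), CXCL10 0.26 ± 0.20 and MS4A1 -0.10 ± 0.15. The count was 1 without bendamustine 1, without combination 1 and with no filter, 2 with GC and length correction and with control 3 and combination 3 left out, and 9 with limma library weights. Ribosomal protein genes had 50 of 50 positive values (camera adjusted p = 8.09e-13; adjusted p = 0.392 with an estimated correlation) and oxidative phosphorylation was positive (camera adjusted p = 7.7e-06; adjusted p = 0.392 with an estimated correlation). With control 3 and combination 3 both left out, the 2 lists turned negative relative to all genes (medians -0.03 and -0.03). Immediate early genes were also higher (camera adjusted p = 0.00143; adjusted p = 0.254 with an estimated correlation), except with control 3 and combination 3 left out (camera adjusted p = 0.0618) or with GC and length correction (0.124).

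Camera called 5 more lists higher in the non-additive contrast: MHC class I (camera adjusted p = 0.0075; adjusted p = 0.39 with an estimated correlation), MHC class II (0.0156; 0.39), cytokines and chemokines (0.016; 0.315), immune ligands (0.0331; 0.254) and endoplasmic reticulum stress (0.0338; 0.254). All 5 calls were absent without combination 3 (camera adjusted p = 0.107, 0.128, 0.107, 0.0562 and 0.0562), as was that of oxidative phosphorylation (0.209). Without control 3 the calls of MHC class II (camera adjusted p = 0.0501), cytokines (0.0762) and ligands (0.0663) were absent. The cytokine call also ended without rituximab 3 (camera adjusted p = 0.0658) or bendamustine 3 (0.0566), and the ligand call without control 1 (0.12), rituximab 3 (0.0658), bendamustine 2 (0.0754) or combination 2 (0.0597). Endoplasmic reticulum stress was not called without control 1 (camera adjusted p = 0.117), control 2 (0.0581), rituximab 2 (0.0531), rituximab 3 (0.0645), bendamustine 1 (0.0752), bendamustine 2 (0.0754) or combination 2 (0.102).

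Across 12422 genes, which are not independent of each other, bendamustine minus control correlated with combination minus rituximab at Pearson r = 0.78, from contrasts that share no library, and 75.8% of genes had the same sign. Of the 2813 genes called with bendamustine, 2778 (98.8%) had the same sign with rituximab present. Both contrasts called 1220 genes higher, against 250 for independent lists, and 730 lower, against 106. No such agreement was seen for rituximab: rituximab minus control and combination minus bendamustine had r = -0.18 and 39.1% of genes with the same sign. With 2 and 0 genes called in these contrasts, this r cannot show whether a rituximab effect carried over. Control 3 is subtracted in the rituximab contrast and combination 3 added in the other, so their like deviations push r down. This r was 0.05 without control 3, 0.10 without combination 3, -0.29 without control 1, -0.12 without rituximab 1 or bendamustine 2, and -0.29 with a filter at 5 FPKM.

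**Figure D4:**
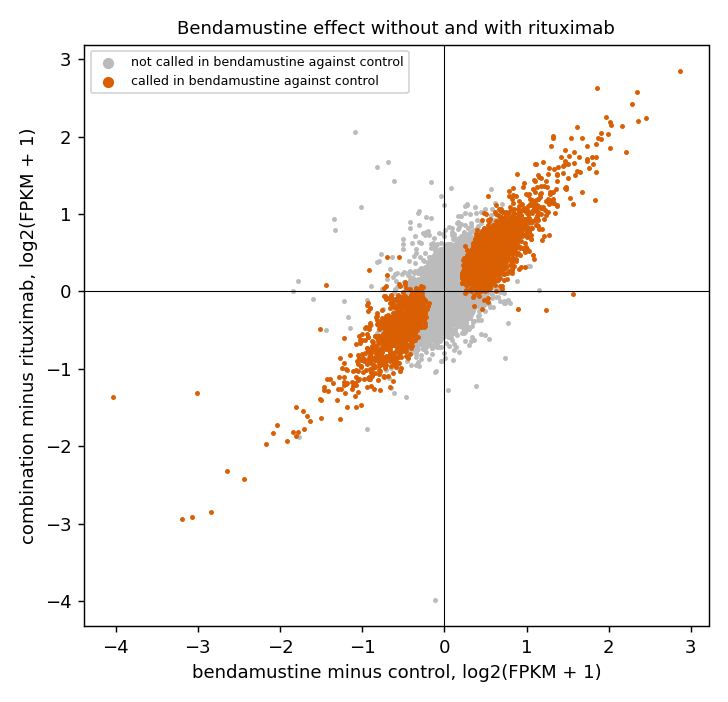
Log2(FPKM+1) difference of bendamustine minus control (horizontal) against combination minus rituximab (vertical), 1 point per tested gene, with genes called between bendamustine and control in orange. Called genes lie along the diagonal.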

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

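For the library that stands apart, the tests of GC content, of exchanged labels and of the trend it shared with control 3 were chosen after the result was seen, as were the SENP3 locus sum and the average rituximab effect. The test of other cell types and the p53 and ATF4 tests were chosen before the data were examined.

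The standard deviation of combination 3 from its group was 1.68 times that of combination 1, the next in the group. The ratio was 1.59 after GC correction and 1.52 after GC and length correction. Its divisor was measured against a mean that includes combination 3, which raises the divisor. The standard deviation of combination 3 itself went from 0.461 to 0.358 after GC correction, so GC content alone does not account for the deviation of this library. Its deviation correlated at r = 0.733 across 7283 genes with that of control 3, a library picked for its like GC trend, and over the tested genes at 0.557, or 0.443 after GC correction, so how much a shared technical trend adds stays open. On 4256 bendamustine-responsive genes it scored 0.156, against -0.285 to -0.210 for libraries without bendamustine and 0.246 to 0.271 for the others with it. This goes against a library without bendamustine under this label. The 16 immediate early genes averaged 4.08 in log2(FPKM+1), against 3.65 to 3.76 with bendamustine alone and 3.94 and 4.03 in combination 2 and 1. That mean was taken without GC correction, so the GC trend of combination 3 may add to it. In control 3, which has a like trend, the mean was 3.31, against 3.29 and 3.33 in control 1 and 2. A bendamustine library under this label is therefore less likely by this value but not excluded. Markers of T cells, myeloid cells, and stroma and epithelium had a largest median excess of 0, and 14 of 17, 12 of 18 and 14 of 17 of them lay under 0.5 FPKM in every combination library, which goes against cells of these types, and other types were not tested. The ribosomal protein and oxidative phosphorylation differences between combination and bendamustine may come from this library, since without it the ribosomal list had a camera adjusted p of 0.636.

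The p53 targets rose while the ATF4 program fell, in the same bendamustine libraries. GC correction left the larger of the 2 adjusted p-values at 0.00149 with camera, and the largest over the 12 fits without 1 library was 0.00275, so neither GC content nor a single library explains the pair. DNA damage from crosslinks could raise the p53 targets, which was not tested. Genes of the ATF4 program were expressed without drug (ASNS 117 FPKM). Whether the fall of this program is a separate response, and what drove it, was not tested.

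The SENP3 locus may show a change in how reads were assigned to transcripts. SENP3-EIF4A1 went from 2.88% to 31.4% of the length-weighted locus sum with rituximab, while SENP3 went from 4.93% to 2.39% and EIF4A1 from 92.2% to 66.2%. With bendamustine the share of SENP3-EIF4A1 was 3.90% and in the combination 2.75%, and that of SENP3 9.07% and 8.18%, so the shift was absent where rituximab was given with bendamustine. The weights were the median lengths of each gene's annotated transcripts: 656.5 bases for SENP3, 3519 for SENP3-EIF4A1 and 642 for EIF4A1. The shares and the sum depend on these lengths, which may differ from those of the transcripts expressed. The sum changed by 0.213 ± 0.124 SE in log2 between control and rituximab. For this reason it cannot decide between reassignment and a true change of transcript.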

How the results depend on the processing

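Requiring a log2 change of at least 1 left 254 genes for bendamustine, 1 for rituximab, 266 for the combination and 273 for the combination against rituximab, because the call is stricter. For the other changes of count, the cause was not tested unless stated. Library weights gave 6166, 27 and 6909 genes against control, 11 for combination against bendamustine, 5724 for combination against rituximab and 9 non-additive. Fitting only the compared groups gave 3361 for bendamustine, 4 for rituximab, 1290 for the combination and 1653 against rituximab. This setting leaves the group differences as they were, so these counts moved through the estimate of spread. No filter gave 5 genes for rituximab, 1 for combination against bendamustine and 1 non-additive, and quantile normalization and no mean-variance trend each gave 1 for combination against bendamustine. GC and length correction gave 2 non-additive genes, as did leaving out both libraries of highest GC deviation, which moved the agreement of the rituximab effect to 0.0216 and of the bendamustine effect to 0.84.

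The labels did not pair the replicates: 7 of 18 pairs with the same number had r above 0.1, against 11 of 36 with different numbers. A replicate block gave 2856, 2, 2819, 0, 2976 and 0 genes, ended the GSDME call in the combination and the cytokine list call with bendamustine, added a glycolysis call with rituximab (camera adjusted p = 0.0256) and changed no other call of a named gene or a list. Without the block the glycolysis list had a camera adjusted p of 0.0726, or 0.618 with an estimated correlation. GC correction with the block gave 4 for rituximab.

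Leaving out 1 library at a time gave ranges of 1888 to 4256 for bendamustine, 1 to 3 for rituximab, 1941 to 3849 for the combination, 0 to 2 for combination against bendamustine, 1976 to 3530 for combination against rituximab and 0 to 1 non-additive. The agreement ranged from -0.29 to 0.10 for the rituximab effect and from 0.70 to 0.85 for the bendamustine effect. The 4256 for bendamustine came without combination 3, which left the difference from control unchanged and altered only the shared estimate of spread. For the other changes the cause was not tested.

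Lists reversed were ribosomal proteins with rituximab (quantile normalization 0.000710, from -0.164 to 0.0306 over the fits without 1 library, both libraries of highest GC deviation left out 0.0306), mitochondrially encoded genes for combination against bendamustine (quantile normalization 0.00857), oxidative phosphorylation for the same contrast (from -0.0248 to 0.291 over the fits without 1 library, both left out -0.0248), and ribosomal proteins (-0.0338) and oxidative phosphorylation (-0.0339) in the non-additive contrast with both left out, as list medians relative to all genes. The cause was not tested.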

Other observations

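Further lists between bendamustine and control held changed genes in both directions. Of 15 heat shock genes, 6 rose and 3 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.764): the chaperones DNAJA1 (94.2 to 160 FPKM, 0.76 ± 0.07 SE) and HSPA1A (2.84 to 5.22, 0.70 ± 0.11) rose. Of 16 NRF2 targets 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.72), with the pentose pathway enzyme TKT at -0.84. Of 23 glycolysis genes 3 rose and 2 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.944). Of 8 complement genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.72), with properdin, CFP, at 0.88. Of 13 plasma cell genes 2 rose and 4 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.0655), with the surface receptor SLAMF7 at 0.79 ± 0.16. Of 34 histone genes 16 were tested, and 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00313, or 0.181 with an estimated correlation), with H2BC5 from 1.6 to 5.54 FPKM. Transcripts of these replication-dependent histone genes lack a poly(A) tail and the libraries were made with a poly(A) kit, so these values may not reflect total histone RNA.

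The average rituximab effect and its lists were tests chosen after the result was seen, and the gene span test was planned before the data were examined.

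Averaged over cells with and without bendamustine, rituximab raised FOS by 0.93 ± 0.10 SE in log2 (limma adjusted p = 0.0144), the 1 gene called. At unadjusted p under 0.05 with limma there were 326 of 12422 genes, again a share below 0.05, and 648 without combination 3. EGR1 had 0.60 ± 0.10 (limma adjusted p = 0.145) and FOSB 0.54 (adjusted p = 0.376), and immediate early genes as a list gave a camera adjusted p of 2.73e-09 (adjusted p = 0.0527 with an estimated correlation). Camera also called ribosomal proteins (adjusted p = 3.76e-05), MHC class I (0.000171), cholesterol synthesis (0.00131), interferon response (0.0123), glycolysis (0.0123), NF-kappaB targets (0.0209) and myeloid genes (0.0315) higher and S phase (0.000113) lower. None of the 9 lists held with an estimated correlation, where cholesterol synthesis had the same adjusted p = 0.0527 as immediate early genes and the others 0.158 to 0.664. The 2 backgrounds could differ: ribosomal proteins had 6 of 50 positive values with rituximab alone and 49 on top of bendamustine. Cholesterol synthesis had a median log2 of 0.0096 on top of bendamustine (camera adjusted p = 0.536). Without combination 3, FOS kept 0.94 (limma adjusted p = 0.0108), while the immediate early list had a camera adjusted p of 0.000131 (adjusted p = 0.202 with an estimated correlation). The other lists of the average effect are not given without combination 3.

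For gene span with bendamustine, the Spearman correlation of log2 change with span was 0.114, and 0.097 after GC correction, and for combination against rituximab -0.166 and -0.084. Without the 3 libraries of highest GC trend the values were 0.0698 and 0.0649, so the negative sign of the latter was not stable. A general loss of long transcripts from DNA lesions is not what the values for bendamustine against control show.

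Regrouping the libraries gave few calls. The real grouping gave 2813 genes for bendamustine against control and the highest other split 1, for rituximab against control 2 and 1, for combination against control 2859 and 2, for combination against bendamustine 0 and 2, and for combination against rituximab 3009 and 0. In each of these 5 contrasts 10 splits were possible, and the splits are too few for a share under 0.05. In the contrasts across bendamustine, each other split mixes libraries with and without the drug in a group. This puts the drug difference into the spread, so few calls there follow from the design and add no evidence. For the non-additive contrast, 100 of 100 drawn regroupings had at least the real count, the highest 3. With a real count of 0 here and for combination against bendamustine, this outcome was fixed in advance and tests nothing.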
